A study of Mus musculus with 12 samples.

How the data were processed

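Myocardial tissue of wild-type mice was profiled by 3′ RNA sequencing in 12 libraries from 10 mice. Per the labels' protocols, total RNA was converted to cDNA with a modified CEL-Seq2 protocol, which primes at the poly(A) tail and reads the 3′ end of transcripts, and each library was amplified without pooling samples. Reads were aligned with STAR and quantified with RSEM on the mouse build GRCm39, with FastQC 0.11.9 for read quality, per the submitters' processing notes. The annotation release, and whether reads were collapsed by molecular identifier or counted by strand, are not given in the sources used here. The authors deposited 2 tables with 1 column per library. The first holds expected counts per gene from RSEM, deposited as whole numbers. The values show the rounding, because each of the 12 libraries has genes with a count of 0 and a TPM above 0. The second holds log2(TPM + 1), deposited by the authors after dividing by effective gene length and scaling each library to the same total. That step weights genes by length although reads from 3′ ends do not grow with length.

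The tables have 57054 gene rows. Of these, 306 had values only in the 2 libraries named 1st and 101 lacked values only there, so the columns were made with different annotations, and the 56647 rows with a value in every library were used. Gene symbols were matched by Ensembl identifier to GENCODE M21 names, which covered 52029 of these rows. That annotation belongs to another genome build than the deposited values, so no coordinates were taken from it. RSEM divides reads among near-identical genes, so values of Ccl21a, H2-Q7 and the ribosomal protein genes, which have close copies or processed pseudogenes, are uncertain. Mitochondrially encoded genes took 16.1% to 24.7% of the counts per library, and 6 nuclear pseudogenes that resemble them took a further 11.9% to 17.5%.

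The mouse was the replicate, with 3 sham vehicle mice, 3 MI mice and 4 NECA-treated MI mice. MI mice 2 and 3 each had a 1st and a 2nd library, whose counts were summed, as fixed before the data were examined. The 1st libraries held 30.8 and 27.1 M counts, against 0.96 to 1.33 M in the 10 others, so they made up 96.9% and 96.6% of the sums. They stood apart in depth and annotation and are treated as a batch. That batch holds MI mice only. Values from the 2nd libraries alone, which together with the other 8 libraries form the second batch, are given as within-batch values. CPM stands for counts per 1e6 counts of a library, and M for 1e6. At 10 CPM a library of the second batch held 9.6 to 13.3 counts, and a count of 0 there allowed up to 3.13 CPM, taken as 3 counts in the smallest library. Such floors cover counting error only.

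Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, scaled with TMM, and compared with the robust quasi-likelihood test in 1 fit over all 10 mice, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. 9688 genes were tested, and 9505 within the batch. CPM values of groups are means over mice after TMM scaling, and errors of log2 fold changes are standard errors. CPM of single libraries, and those said to be relative to library totals, are divided by the summed counts of the library or mouse. Scaling moved the median of all genes by at most 0.1 on the log2 scale against no scaling. On counts simulated from these mice with 200 changed genes, the test recovered 25% of the 2-fold and 92.5% of the 4-fold changes for MI against sham vehicle, 32.5% and 94% for NECA-treated MI against MI, and 29% and 87.5% for NECA-treated MI against sham vehicle, over 9688 genes each.

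41 gene lists for cell types and pathways were fixed before the data were examined, of which 35 had at least 3 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A list's score in a mouse is the mean over its members of log2 CPM (prior count 2) minus the sham vehicle mean. Counts of list members are given over all genes and adjusted over the list alone. Named genes followed a rule fixed beforehand. It took the 6 largest rises and falls among genes past the threshold with at least 10 CPM, an established symbol and no overlap of the groups. Where fewer than 3 genes passed in a direction, it took the 5 genes of smallest p. It added 2 members of each of up to 8 passing lists, the adenosine receptor genes and Nt5e. Genes named outside it are said to be chosen after their values were seen. Other scalings, DESeq2 1.42.0, limma on log2(TPM + 1), no count filter, single libraries, a fit of the 2 groups alone, a block and leaving out each mouse were run as alternatives. Correlations of fold changes that share mice were set against 40 simulations of unchanged groups with the fitted dispersions. Each gene was drawn independently in them, so they hold no correlation between genes. No column was left out of the tables. The labels number the mice within each group, and give neither the time after ligation nor the dose of NECA.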

Results

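Transcripts of heart muscle were measured in 3 groups of mice. Of these, 3 mice carried labels of both sham surgery and vehicle and are called sham vehicle mice. A further 3 had the left coronary artery ligated, which causes myocardial infarction (MI), and 4 had the ligation together with local delivery of NECA, 5′-(N-ethylcarboxamido)adenosine, a stable adenosine analogue that activates adenosine receptors. The titles of the MI mice name neither vehicle nor delivery. If they received none, NECA cannot be told apart from its delivery, nor ligation from the absence of vehicle. The 10 libraries of lower depth held 0.96 to 1.33 M counts, and the 1st libraries of MI mice 2 and 3 held 30.8 and 27.1 M. The repeated libraries of a mouse correlated at r = 0.913 for MI mouse 2 and 0.957 for MI mouse 3 across genes, which are not independent replicates. The 2nd library of MI mouse 2 correlated better with a library of another mouse (r = 0.928) than with its own 1st library, and the pair was the best correlate for 3 of the 4 repeated libraries. Between the 1st and 2nd libraries 25 of 14710 genes differed, 6 higher and 19 lower in the 1st (edgeR, adjusted p under 0.05). They differed by more than counting noise, with chi-square values of 13 and 2.21 per gene.

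Single mice stood apart in markers of other tissues and of strained ventricle. The markers belonged to lists fixed beforehand, and those named here were chosen after their values were seen. Sham vehicle mouse 3 had 1350 CPM of Myl4 and 785 CPM of Myl7, light chains of atrial myosin, and 285 CPM of the atrial calcium pump regulator Sln, against at most 8.26, 0.888 and 1.78 CPM in any other library. It also had 108 CPM of the fat cell hormone Adipoq, against 0 CPM in the other sham vehicle mice and at most 23.1 CPM elsewhere. MI mouse 3 had 3590 CPM of Myh7, the slow myosin heavy chain induced in strained ventricle, in its 1st library and 2940 CPM in its 2nd, against 152 to 282 CPM in MI mice 1 and 2. Skeletal muscle transcripts appeared in NECA-treated mouse 4, with 97.9 CPM of Myh4 and 45.2 CPM of Tnnt3, and in both libraries of MI mouse 2, with 12.9 and 12.3 CPM of Tnnt3.

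**Figure D1:**
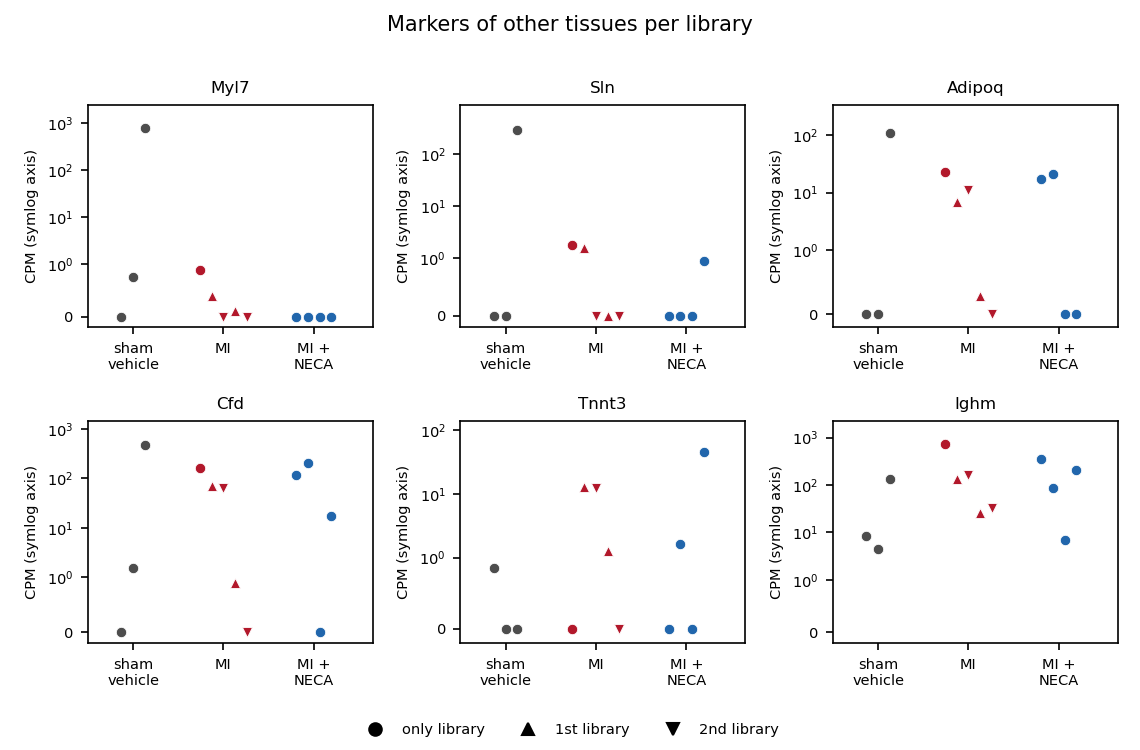
CPM (symmetric log axis, linear below 1) of atrial (Myl7, Sln), fat (Adipoq, Cfd), skeletal muscle (Tnnt3) and B cell (Ighm) transcripts, 1 point per library, with triangles for the 1st and 2nd libraries of MI mice 2 and 3. Sham vehicle mouse 3 lies highest for Myl7 (785 CPM), Sln (285 CPM) and Adipoq (108 CPM), and NECA-treated mouse 4 for Tnnt3 (45.2 CPM).

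After coronary ligation, transcripts of an endosomal tetraspanin and a lymphatic chemokine rose, and those of a retinoic acid hydroxylase and a beta tubulin fell. Cd63 (ENSMUSG00000025351), a tetraspanin of late endosomes and exosomes, rose from 34.3 ± 5.96 CPM in sham vehicle mice to 90.5 ± 17.8 CPM in MI mice (SD, n = 3 each), a log2 fold change of 1.41 ± 0.21 (SE, edgeR adjusted p = 0.0106). Ccl21a (ENSMUSG00000094686), a chemokine of lymphatic vessels with near-identical copies in the mouse genome, rose by 1.87 ± 0.30 (adjusted p = 0.0173). Tspan13, another tetraspanin, the glucocorticoid-induced regulator Tsc22d3, the transcription factor Klf2 of endothelium and T cells, and Tcim rose by 1.19, 1.09, 1.08 and 1.08. Cyp26b1 (ENSMUSG00000063415), which degrades retinoic acid, fell from 19.0 ± 10.8 to 2.59 ± 1.68 CPM (log2 fold change -3.29 ± 0.49, adjusted p = 0.0106), and within the batch it had -2.48 and did not pass (adjusted p = 0.0584). Tubb4b (ENSMUSG00000036752), a beta tubulin, fell from 264.3 ± 39.9 to 121 ± 17.8 CPM (log2 fold change -1.13 ± 0.19, adjusted p = 0.024). The magnesium transporter gene Slc41a3, the bicarbonate transporter gene Slc4a4, Nt5dc3 and Pdzd2 fell by 1.42, 1.14, 1.11 and 1.09 on the log2 scale. Of 9688 genes tested, 7 rose and 8 fell in MI against sham vehicle mice. The 3 MI mice lay wholly above or below the 3 sham vehicle mice in all 15, a separation that 15.2% of all tested genes showed and chance gives in 10%. Within the batch, 4 genes rose and 3 fell among 9505, and all 15 genes above had the same sign. The within-batch fit shares its mice with the main fit, so this is not an independent test. The 5 shared genes were Cd63, Ccl21a, Tcim, Tubb4b and 2410006H16Rik, the last of them named after its value was seen. The count was 0 without sham vehicle mouse 1 or 2 (1090 and 1008 genes at an unadjusted p under 0.05), 40 without sham vehicle mouse 3 (7 of them among the 15), 310, 67 and 5 without MI mouse 1, 2 or 3 (15, 15 and 4 among the 15), and 3, 3, 3 and 5 without NECA-treated mice 1 to 4. It was 92 with DESeq2.

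**Figure D2:**
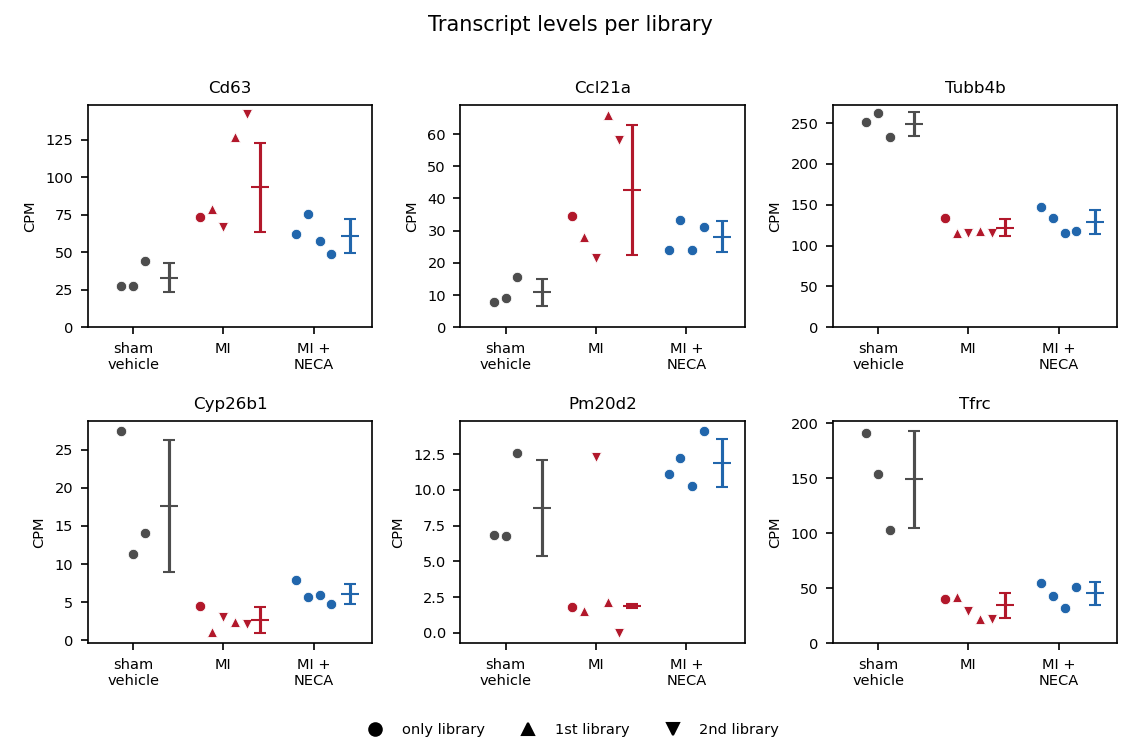
CPM of 6 genes, 1 point per library, with the mean ± SD over mice beside each group (n = 3, 3 and 4) and triangles for the 1st and 2nd libraries of MI mice 2 and 3. Cd63 and Ccl21a were lower and Tubb4b, Cyp26b1 and Tfrc higher in each sham vehicle mouse than in each infarcted mouse, whereas Pm20d2 was 1.56 CPM in the 1st and 12.3 CPM in the 2nd library of MI mouse 2.

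Of the 35 gene lists tested in MI against sham vehicle mice, 11 passed camera upwards and 2 downwards, 12 of these 13 also within the batch. None passed with an estimated correlation (smallest adjusted p = 0.446) or with fry (smallest adjusted p = 0.106), so the list results below describe a shared direction of members. No member of these lists passed over all genes. Macrophage and monocyte markers were higher in all 16 members, of which 12 rose when adjusted over the list alone, with a median log2 fold change of 1.30 (camera adjusted p = 6.05e-12, adjusted p = 0.446 with an estimated correlation) and 1.26 within the batch. The lysozyme gene Lyz2 was 328 ± 149 CPM in MI and 132 ± 51.8 CPM in sham vehicle mice, and the signalling adaptor gene Tyrobp 20.4 ± 10.4 and 7.23 ± 1.29 CPM. Collagen and matrix genes had positive fold changes in all 38 members, 1 of which rose when adjusted over the list alone (median 1.76, camera adjusted p = 1.81e-10, adjusted p = 0.544 with an estimated correlation). The matrix metalloproteinase gene Mmp2 was 129 ± 107 CPM in MI and 26.7 ± 11.7 CPM in sham vehicle mice, and Ccn1, a secreted matricellular protein gene, had a log2 fold change of 1.08 ± 0.26. The collagen score was 3.14 and 3.20 in the 2 libraries of MI mouse 3 and 0.28 to 0.73 in those of MI mice 1 and 2, beside -0.41, -0.41 and 0.82 in the sham vehicle mice. Without MI mouse 3 the medians of the macrophage and collagen lists were 0.71 (camera adjusted p = 9.37e-07) and 0.28 (camera adjusted p = 0.014), with adjusted p = 0.681 and 0.877 with an estimated correlation. Without sham vehicle mouse 3 they were 1.67 and 2.40. That mouse scored 0.80 for macrophage markers, above MI mouse 2 (0.77) and below MI mice 1 and 3 (1.18 and 2.20).

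Ion channel and calcium handling genes were lower in 22 of 24 members, of which 7 fell when adjusted over the list alone (median -0.53, camera adjusted p = 3.71e-09, adjusted p = 0.446 with an estimated correlation), and the within-batch median was -0.39. The potassium channel gene Kcnh2 had a log2 fold change of -0.99 ± 0.21 and the pacemaker channel gene Hcn4 of -1.36 ± 0.35. Relative to library totals, Hcn4 was 12.8 to 28.3 CPM in sham vehicle mice and up to 13.3 CPM in MI mice. The highest of these values was that of sham vehicle mouse 3, which held atrial transcripts. Ribosomal protein genes were higher in 29 of 30 members, 19 of which rose when adjusted over the list alone (median 0.48, camera adjusted p = 6.05e-12, adjusted p = 0.446 with an estimated correlation). Their within-batch median was 0.27, and with MI mouse 3 also left out it was 0.07 (camera adjusted p = 0.197). Rpl19 and Rpl32 had log2 fold changes of 0.65 ± 0.20 and 0.60 ± 0.18. Inflammatory cytokines and chemokines were higher in all 9 members, with 3 past the threshold when adjusted over the list alone (median 0.86, camera adjusted p = 3.14e-05, adjusted p = 0.446 with an estimated correlation), among them the adhesion molecule gene Vcam1 (0.86 ± 0.28) and the chemokine gene Ccl9 (1.40 ± 0.48, within the batch 0.85).

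Antigen presentation genes had a median of 0.61 in MI against sham vehicle mice, with 12 of 14 members higher and 0 past the threshold when adjusted over the list alone (camera adjusted p = 6.72e-05, adjusted p = 0.485 with an estimated correlation). Their within-batch median was 0.39. Sham vehicle mouse 3 scored 0.65 for this list, above MI mice 1 and 2 (0.47 and 0.36) and below MI mouse 3 (1.06). The class II gene H2-Ab1 and the immunoproteasome gene Psmb8 had log2 fold changes of 1.38 ± 0.41 and 0.77 ± 0.28. Resident and reparative macrophage markers had a median of 0.56 (camera adjusted p = 0.0204, adjusted p = 0.544 with an estimated correlation). Spp1, the gene for osteopontin, had no count in any sham vehicle mouse and, relative to library totals, 13 ± 16.9 CPM in MI mice. This was at least 16.4-fold more than the 0.796 CPM that 3 counts over the sham vehicle group make, and at least 4.11-fold without MI mouse 3, the highest at 32.5 CPM. The lysosomal glycoprotein gene Gpnmb had a log2 fold change of 1.41 ± 0.70. Autophagy and lysosome genes had a median of 0.13 (camera adjusted p = 0.0204, adjusted p = 0.446 with an estimated correlation), and within the batch they did not pass (0.06, camera adjusted p = 0.0718). Their members of smallest p were the cathepsin gene Ctsk (2.34 ± 0.58) and Gabarap (0.55 ± 0.18). Complement and coagulation genes (0.40), fibroblast and myofibroblast markers (0.62), nuclear retained RNA (0.73) and B cell markers (2.41) passed upwards and fatty acid oxidation genes (-0.19) downwards. In this order camera gave adjusted p of 0.0204, 0.0238, 0.0274, 0.0476 and 0.0426, and adjusted p of 0.544, 0.668, 0.446, 0.485 and 0.693 with an estimated correlation. Their within-batch medians were 0.32, 0.74, 0.29, 2.49 and -0.22. Without MI mouse 3 their medians were 0.16, -0.01, 0.68, 2.81 and 0.06, and only B cell markers passed (camera adjusted p = 0.014, adjusted p = 0.681 with an estimated correlation). The nuclear retained RNA list also held the small nucleolar RNA host genes Gas5 and Snhg1. Sham vehicle mouse 3 scored 0.97 for complement genes, above all 3 MI mice (0.23 to 0.90). Its fibroblast score of 0.73 lay above MI mice 1 and 2 (0.44 and 0.08) and below mouse 3 (1.79), and its B cell score of 2.66 above MI mouse 3 (1.25). Contractile genes of cardiomyocytes (median -0.14, camera adjusted p = 0.0645) and fetal and stretch genes (0.18, camera adjusted p = 0.438) did not pass. Within the batch 7 further lists passed camera. Contractile genes (-0.21), oxidative phosphorylation genes (-0.18), glycolysis and hypoxia genes (-0.20) and erythroid markers (-0.51) were lower, and endothelial markers (0.19), pericyte and smooth muscle markers (0.38) and apoptosis genes (0.32) higher. In this order camera gave adjusted p of 0.0231, 0.0416, 0.0272, 0.0231, 0.0458, 0.00653 and 0.0467, and adjusted p of 0.693, 0.693, 0.41, 0.546, 0.41, 0.41 and 0.41 with an estimated correlation.

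**Figure D3:**
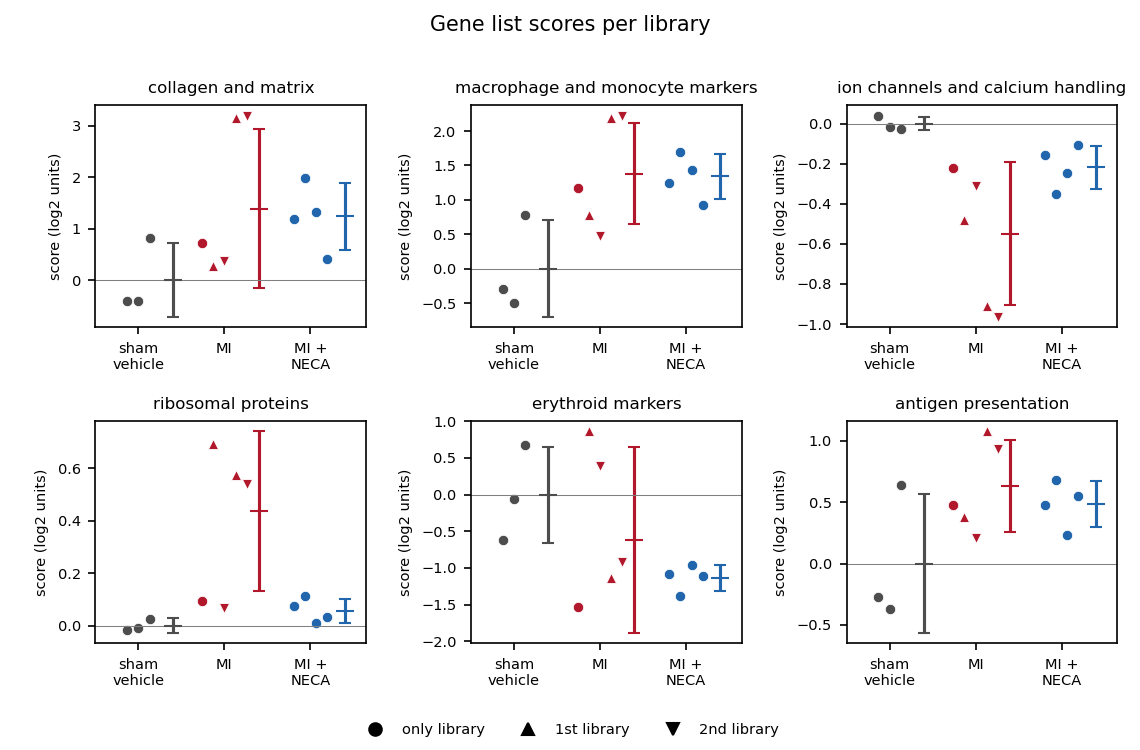
Scores of 6 gene lists (mean over members of log2 CPM minus the sham vehicle mean), 1 point per library, with the mean ± SD over mice beside each group (n = 3, 3 and 4) and triangles for the 1st and 2nd libraries of MI mice 2 and 3. MI mouse 3 lies highest for collagen and matrix (3.14 and 3.20), and the ribosomal protein score of MI mouse 2 is 0.69 in its 1st and 0.07 in its 2nd library.

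Against MI alone, 1 transcript passed as higher with local delivery of NECA when all libraries were used, but not within the batch. It was Pm20d2 (ENSMUSG00000054659), a member of the M20 peptidase family, at 12.05 ± 1.93 CPM in 4 NECA-treated mice and 1.89 ± 0.19 CPM in 3 MI mice (log2 fold change 2.63 ± 0.38, adjusted p = 0.0145). Its level was 1.56 CPM in the 1st and 12.3 CPM in the 2nd library of MI mouse 2, and within the batch its log2 fold change was 1.34 (adjusted p = 0.812). Of 9688 genes, 1 rose and 0 fell by edgeR's test, with 1060 at an unadjusted p under 0.05, and DESeq2 called 5 other genes, all higher. No gene passed within the batch (edgeR, smallest adjusted p = 0.793), where 577 genes had an unadjusted p under 0.05. By the rule for a direction with few calls, the next genes on the higher side were Dcaf1, a substrate receptor of a ubiquitin ligase, Myocd, the myocardin coactivator of muscle genes, and Arel1, with log2 fold changes of 1.05, 1.27 and 0.88, and Tbc1d16, at 85.8 ± 5.89 CPM with NECA and 45.6 ± 18.6 CPM without it. None of these passed (smallest adjusted p = 0.27). Within the batch the log2 fold changes of Dcaf1, Myocd, Arel1 and Tbc1d16 were 0.90, 0.60, 0.43 and 0.49. On the lower side Rpl22l1 (-1.33), the small nucleolar RNA host gene Gas5 (-0.95), Phax (-1.27), the immediate early transcription factor gene Egr1 (-1.48) and Rpl36a (-0.75) did not pass either, and within the batch they had -0.64, -0.99, -1.06, -1.46 and -0.52. Egr1 was 7.92 ± 3.24 CPM with NECA and 21.5 ± 6.90 CPM without it. The count was 121 without MI mouse 1 and 0 without MI mouse 2 or 3 or any of the NECA-treated mice (744 to 1361 genes at an unadjusted p under 0.05).

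In NECA-treated MI against MI mice, 1 list passed camera upwards and 3 downwards, none of them with an estimated correlation (smallest adjusted p = 0.712) or fry (0.244). All 30 ribosomal protein genes had negative fold changes, and 16 fell when adjusted over the list alone (median -0.44, camera adjusted p = 2.9e-13, adjusted p = 0.855 with an estimated correlation). Rps19 and Rpl27 had log2 fold changes of -0.56 ± 0.18 and -0.51 ± 0.17, and within the batch of -0.26 and -0.19. The within-batch median of this list was -0.17 (camera adjusted p = 0.00043, adjusted p = 0.784 with an estimated correlation) and, with MI mouse 3 also left out, -0.00787 (camera adjusted p = 0.883). Ion channel and calcium handling genes were higher in 20 of 24 members and 0 rose when adjusted over the list alone (median 0.35, camera adjusted p = 8.84e-05, adjusted p = 0.855 with an estimated correlation), with 0.21 within the batch and 0.13 without MI mouse 3 (camera adjusted p = 0.218). The junctophilin gene Jph2 was 417 ± 23.3 CPM with NECA and 291 ± 80.1 CPM without it. The list named nuclear retained RNA was lower in all 5 members (median -0.27, camera adjusted p = 0.0399, adjusted p = 0.712 with an estimated correlation). The 2 members that fell when adjusted over the list alone were the small nucleolar RNA host genes Gas5 and Snhg1 (-1.27 ± 0.41 for Snhg1, within the batch -0.73). The list thus does not show a fall of retained RNA in general. Inflammatory cytokines and chemokines were lower in all 9 members with 0 past the threshold over the list alone (median -0.36, camera adjusted p = 0.0449, adjusted p = 0.855 with an estimated correlation), and did not pass within the batch (-0.38, camera adjusted p = 0.105). The chemokine gene Ccl9 and the NF-kappa-B inhibitor gene Nfkbia had log2 fold changes of -1.03 ± 0.42 and -0.32 ± 0.20, and within the batch of -0.49 and -0.11. Without MI mouse 3 that of Ccl9 was -0.64. Fatty acid oxidation genes passed upwards within the batch only (median 0.18, camera adjusted p = 0.00043, adjusted p = 0.796 with an estimated correlation). With all libraries their median was 0.05 (camera adjusted p = 0.0679). MI mouse 3 scored -0.94 for this list, against -0.08 and 0.19 in MI mice 1 and 2.

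Collagen and matrix genes had a median of -0.61 in NECA-treated MI against MI mice (camera adjusted p = 0.0986, adjusted p = 0.867 with an estimated correlation) and -0.58 within the batch (camera adjusted p = 0.0283, adjusted p = 0.853 with an estimated correlation). Without MI mouse 3 the median was 0.81 (camera adjusted p = 1.74e-07, adjusted p = 0.966 with an estimated correlation). Macrophage and monocyte markers likewise had a median of -0.26 (camera adjusted p = 0.569) and, without MI mouse 3, 0.35 (camera adjusted p = 0.0168, adjusted p = 0.966 with an estimated correlation). Of the adenosine receptor genes, Adora1 was 10.5 ± 2.92 CPM with NECA, 9.05 ± 0.36 CPM in MI and 16.6 ± 7.27 CPM in sham vehicle mice, and Adora2a 7.89 ± 1.78, 8.70 ± 1.07 and 7.34 ± 3.92 CPM. The ectonucleotidase gene Nt5e, which makes adenosine from AMP, was 17.1 ± 5.93, 12.8 ± 3.66 and 9.68 ± 0.91 CPM. None of these 3 passed the threshold in any comparison (smallest adjusted p = 0.22, for Adora1 in MI against sham vehicle mice). Against sham vehicle mice and without overlap after TMM scaling, Adora1 was lower in MI (-0.89 ± 0.32) and Nt5e higher with NECA (0.82 ± 0.33). Of all tested genes, 15.2% and 8.52% showed such a separation in these comparisons. Relative to library totals Adora1 did overlap, at up to 11 CPM in MI and from 10.3 CPM in sham vehicle mice. Its highest sham vehicle value, 26.7 CPM, was that of mouse 3, which held atrial transcripts. The test missed most simulated 2-fold changes, so a difference is not excluded. Adora2b had 0 to 5 counts and Adora3 0 to 2 counts in each library of lower depth, too few to detect a difference.

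Against sham vehicle mice, the beta tubulin transcript Tubb4b passed as lower in NECA-treated MI mice within the batch, and no gene passed with all libraries. Both fits used the same libraries of these 2 groups and differed only in the counts of MI mice 2 and 3. Those counts enter the shared filter, scaling and estimate of spread. Tubb4b was 130 ± 13.2 CPM in 4 NECA-treated and 264.3 ± 39.9 CPM in 3 sham vehicle mice (within-batch log2 fold change -1.02, adjusted p = 0.0127, edgeR). With all libraries its log2 fold change was -1.025 (edgeR adjusted p = 0.15). With all libraries 0 of 9688 genes passed edgeR's test (smallest adjusted p = 0.15, 411 genes at an unadjusted p under 0.05), and 4 did with DESeq2. By the rule for directions without calls, the genes of smallest p on the higher side were the clock genes Per2 (log2 fold change 1.43 ± 0.28) and Per3 (1.35 ± 0.27), Ccl21a (1.32), the class I gene H2-Q7 (1.14), which has near-identical neighbours, and Cd63 (0.83). On the lower side they were Tubb4b, Slc41a3 (-1.10), the transferrin receptor gene Tfrc (-1.82 ± 0.36), Alas1 (-0.86), which encodes the first enzyme of haem synthesis, and the cytokine signalling inhibitor gene Cish (-0.76). Tfrc was 45.6 ± 10.8 CPM with NECA and 161 ± 61.6 CPM in sham vehicle mice. The count was 1 without sham vehicle mouse 1, 1 without MI mouse 2 and 2 without MI mouse 3.

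In NECA-treated MI against sham vehicle mice, 8 lists passed camera upwards and 2 downwards, and none with an estimated correlation (smallest adjusted p = 0.479) or fry (0.55). Macrophage and monocyte markers were higher in all 16 members, 3 of which rose when adjusted over the list alone (median 1.04, camera adjusted p = 3.28e-20, adjusted p = 0.479 with an estimated correlation). Lyz2 was 303 ± 60.6 CPM and the endosomal glycoprotein gene Cd68 13.6 ± 1.39 against 4.5 ± 0.72 CPM. Collagen and matrix genes were higher in 33 of 38 members and 0 rose over the list alone (median 1.09, camera adjusted p = 1.18e-12, adjusted p = 0.484 with an estimated correlation). Mmp2 was 82.2 ± 30.5 CPM, and the matricellular gene Postn had a log2 fold change of 2.72 ± 1.25. The sham vehicle score of this list was 0.82 in mouse 3 and -0.41 in mice 1 and 2, and without mouse 3 the medians of the collagen and macrophage lists were 1.64 and 1.55. Erythroid markers were lower in all 6 members and 1 fell over the list alone (median -1.29, camera adjusted p = 6.61e-07, adjusted p = 0.479 with an estimated correlation). Bpgm was 17.4 ± 4.88 against 34.7 ± 7.49 CPM, and Alas2 had a log2 fold change of -1.30 ± 0.62. Antigen presentation genes had a median of 0.43 (camera adjusted p = 0.00013, adjusted p = 0.479 with an estimated correlation), with Nlrc5 at 1.11 ± 0.53 and Psmb8 at 0.56 ± 0.29. Sham vehicle mouse 3 scored 0.65 for this list, within the 0.24 to 0.68 of the NECA-treated mice. Relative to library totals, Spp1 was 8.65 ± 7.09 CPM and the acute-phase gene Saa3 6.66 ± 6.5 CPM with NECA, and neither had a count in sham vehicle mice. These were at least 10.9-fold and 8.36-fold above the 0.796 CPM that 3 counts over that group make. Without NECA-treated mouse 2, the highest for both genes (17.9 CPM of Spp1 and 15.5 CPM of Saa3), they were at least 7-fold and 4.68-fold above it. Resident and reparative macrophage markers (0.29, with Gpnmb at 1.74 ± 0.72), inflammatory cytokines and chemokines (0.37, with Vcam1 at 0.50 ± 0.29), pericyte and smooth muscle markers (0.31, with Rgs5 at 0.60 ± 0.20 and Vtn at 0.53 ± 0.34), complement and coagulation genes (0.23) and B cell markers (1.57) passed upwards. In this order camera gave adjusted p of 0.00091, 0.00282, 0.00574, 0.017 and 0.0466, and adjusted p of 0.479, 0.479, 0.479, 0.631 and 0.479 with an estimated correlation. Ion channel genes passed downwards (median -0.27, camera adjusted p = 0.00282, adjusted p = 0.526 with an estimated correlation), with Kcnh2 at -0.60 ± 0.20 and Hcn4 at -1.02 ± 0.35. The highest sham vehicle value of Hcn4, 28.3 CPM of library totals, was that of mouse 3, which held atrial transcripts. B cell markers did not pass within the batch (camera adjusted p = 0.0762). Sham vehicle mouse 3 scored 0.97 for complement genes, above all NECA-treated mice (-0.18 to 0.90). Its B cell score of 2.66 lay above NECA-treated mice 2 and 3 (2.41 and -1.06) and below mice 1 and 4 (4.08 and 3.47). Its resident macrophage score of 0.68 lay above NECA-treated mouse 4 (0.59). The median of complement genes turned negative without sham vehicle mouse 2, and that of resident macrophage markers without NECA-treated mouse 2.

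Whether NECA moved transcripts against the direction of MI was asked across genes, which are not independent replicates. The log2 fold changes of MI against sham vehicle and of NECA-treated MI against MI correlated at r = -0.60 over 9688 genes. Both share the MI mice with opposite sign, and 40 simulations of unchanged groups gave a mean r of -0.453 (-0.52 to -0.393). Genes were drawn independently in these simulations, whereas members of lists moved together. In MI against sham vehicle mice the estimated correlation was 0.877 for collagen and 0.691 for ribosomal protein genes. The simulated ranges are therefore too narrow, and a value beyond them does not show opposition. The covariance was -0.117 against -0.0634 in the simulations, a difference of -0.0531. Signs were opposite in 75.8% of genes, against 64.7% in the simulations. Pm20d2 passed in both comparisons, which share the MI mice, and within the batch in neither (adjusted p = 0.598 and 0.812). Within the batch r was -0.595, against -0.583 as the lowest simulated value, and the covariance difference was -0.0186. Without MI mouse 3, r was -0.567, inside the simulated range of -0.628 to -0.478, while the covariance (-0.131 against -0.127 as the lowest simulated) and the share of opposite signs (76.2% against at most 69.3%) lay beyond it. Without sham vehicle mouse 3, r was -0.477, inside the range of -0.487 to -0.315, while the covariance (-0.141 against -0.0904) and the share (72.8% against at most 63.9%) lay beyond it. The log2 fold changes of both infarcted groups against the shared sham vehicle mice correlated at r = 0.726 (0.583 simulated), with a covariance of 0.164 against 0.0894. The 3 mice of a shared group were too few to be split, so part of either excess may come from shared mice. Part may also come from genes that move together, which the simulations left out.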

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

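All tests of technical explanations in this part were chosen after the results were seen, whereas the comparisons with other splits of the mice were planned. Among 81 sets of 4 NECA-treated values, 5 had 1 mouse far from the rest by Dixon's criterion, about the 1 in 20 that chance gives. Their CPM are after TMM scaling. Adora1 was far out (ratio 0.882), at 14.9 CPM in NECA-treated mouse 2 and 8.82 to 9.54 CPM in the others, and Nt5e (0.904), at 26 CPM in mouse 3 and 13.6 to 14.8 CPM in the others. So were Cd68 (0.938), at 15.7 CPM in mouse 2 and 12.8 to 13 CPM in the others, Nlrc5 (0.891), at 17.8 CPM in mouse 4 and 8.62 to 9.62 CPM in the others, and the score of cAMP and immediate early response genes (0.866), at 0.07 in mouse 1 and -0.13 to -0.10 in the others. Genes with values only in the 2 libraries named 1st, and so outside every comparison, held 19104 counts in 86 genes, 0.033% of the counts of those libraries.

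Ribosomal protein transcripts were lower in NECA-treated MI than in MI mice, at a median log2 fold change of -0.44. In MI mouse 2 the 1st library scored 0.625 above the 2nd, against an SD of 0.0446 among NECA-treated mice, as a batch of the 1st library would give. A fault of the 2nd library stays open too, since it correlated at 0.928 with a library of another mouse and at 0.913 with the 1st, whereas Tnnt3, at 12.9 and 12.3 CPM in the 2 libraries, at most 1.63 CPM in 8 of the other mice and 45.2 CPM in NECA-treated mouse 4, argues against a library of another of these mice. In MI mouse 3 the 2nd library alone still scored 0.539, within 0.0358 of the 1st, which argues against the batch there. With the 2nd libraries alone and no MI mouse 3 the median was -0.00787, so the difference rests on that mouse and on the 1st library of MI mouse 2, and an effect of NECA stays open.

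Collagen and matrix transcripts were highest in MI mouse 3, and the direction of the comparison of NECA-treated MI with MI mice depended on it. Its 2nd library scored 3.20, above each library of the other mice, which argues against the batch of the 1st library. Atrial tissue would have brought Myl7 with the Nppa of this mouse, to about 833 CPM at the ratio of sham vehicle mouse 3, and Myl7 was 0.111 CPM. Fat in the piece is argued against by Cfd, a fat cell transcript, at 0.885 CPM, below MI mice 1 and 2. The extent of the infarct and the share of scar in the piece, or a difference between mice in the response to ligation, may account for it, and neither was measured.

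In sham vehicle mouse 3, of 9 atrial markers above 1 CPM, 5 were higher there than in every other library (Myl4, Myl7, Sln, Bmp10 and Stard10), and so were 12 of 12 adipocyte markers, where chance gives 1 in 12. So were 9 of 12 epicardial and mesothelial markers, among them Upk3b at 194 CPM against at most 88.8 CPM. Myh7, which a load response of ventricular muscle would raise, was 99.8 CPM, not above the other sham vehicle mice. The values are consistent with atrial tissue, fat and epicardium in the piece, with epicardium not tested apart from the others, and the load response was the only biological explanation tested. Without this mouse the changed genes in MI against sham vehicle mice numbered 40 in place of 15, and within the batch 50 in place of 7. Each of these 2 sets held only 7 of the 15 genes called with all mice and libraries.

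For MI against sham vehicle mice there are 10 splits of the 6 mice, too few for a share under 0.05. The real split gave 15 genes, the highest other 108, and 2 splits, the real one among them, gave at least 15. The split with 108 set sham vehicle mice 1 and 2 with MI mouse 2 against the rest, which points to a structure of the samples other than the groups. For NECA-treated MI against MI mice, 5 of 35 splits gave at least the 1 gene of the real split, the highest other 5, so chance was not excluded. For NECA-treated MI against sham vehicle mice the real split gave 0 genes, the highest other 0. Each of the 35 splits reaches 0 by definition, so this says nothing about chance. Within the batch, where Tubb4b passed, 5 of 35 splits gave at least 1 gene, the highest other 7, so chance was not excluded.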

How the results depend on the processing

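The alternatives that combine the 2nd libraries with a left-out mouse, the gene list tests on the 2nd libraries, the estimated correlations with them or with a mouse left out, and the bounds of Spp1 and Saa3 without the highest mouse were chosen after seeing the data, and all others were planned. For MI against sham vehicle mice (15 genes), the count was 12 to 15 with DESeq2's size factors in edgeR, the 1st libraries alone, a fold of at least 2, and without mitochondrial and haemoglobin genes. It was 92 with DESeq2 (11 shared), 346 without the count filter (15 shared), 0 with only the 2 groups fitted (880 at an unadjusted p under 0.05), 7 with the 2nd libraries alone, 30 with the 5 MI libraries as separate samples, 0 with limma on log2(TPM + 1) (906 at an unadjusted p under 0.05), 50 with the 2nd libraries alone and no sham vehicle mouse 3, 1 with the 2nd libraries alone and no MI mouse 3, and 0 to 310 without 1 mouse. For NECA-treated MI against MI mice (1 gene) it was 5 with DESeq2 (0 shared), 74 without the count filter, 0 with the 2nd libraries alone, with either of the further mice left out as well, with 5 separate MI libraries and with limma (520 at an unadjusted p under 0.05), and 0 to 121 without 1 mouse. For NECA-treated MI against sham vehicle mice (0 genes) it was 4 with DESeq2, 27 without the count filter, 7 with only the 2 groups fitted, 1 with the 2nd libraries alone, 5 and 7 with no sham vehicle mouse 3 or no MI mouse 3 as well, and 0 to 2 without 1 mouse. The correlation of both effects was -0.689 to -0.477 without 1 mouse, inside the simulated range of r without sham vehicle mouse 3 or MI mouse 3, where covariance and share of opposite signs lay beyond theirs, and beyond it in the other fits that were simulated. The simulated genes were independent, so these ranges are too narrow to show opposition. The cause of these shifts was not tested. At 0.96 to 1.33 M counts in most libraries, genes near 10 CPM rest on about 10 counts.

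Among the named genes and the lists past camera with all libraries, direction turned for few, none of them past the threshold after turning. Other lists did pass after turning. In NECA-treated MI against MI mice, collagen genes passed downwards within the batch and upwards without MI mouse 3, where macrophage markers also turned and passed upwards. Oxidative phosphorylation genes in MI against sham vehicle mice had medians of 0.04 with all libraries and -0.18 within the batch, where they passed. The median of fatty acid oxidation genes in MI against sham vehicle mice ran from -0.47 to 0.0613 without 1 mouse, and that of fibroblast markers was -0.00824 without MI mouse 3. In NECA-treated MI against sham vehicle mice the median of complement genes was -0.0411 without sham vehicle mouse 2, and that of resident macrophage markers -0.00157 without NECA-treated mouse 2. Adora2a in MI against sham vehicle mice (0.28) was -0.11 with the 2nd libraries alone, -0.11 with limma, -0.46 and -0.43 with sham vehicle mouse 3 or MI mouse 3 also left out, and -0.0745 to 0.79 without 1 mouse. In NECA-treated MI against MI mice, Adora2a (-0.16) was 0.22 with the 2nd libraries alone, 0.36 with limma, and 0.23 and 0.54 with those mice also left out, Rps19 was 0.0435 with the 2nd libraries alone and no MI mouse 3, Ccl9 was 0.0835 with limma, and Adora1 ran from -0.0141 to 0.29 without 1 mouse. Adora2a in NECA-treated MI against sham vehicle mice was -0.24 with the 2nd libraries alone and no sham vehicle mouse 3, and -0.24 to 0.62 without 1 mouse.

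The groups share mouse numbers in the labels. With the number as a replicate block the counts were 6, 0 (744 at an unadjusted p under 0.05) and 1 gene in the order above, and r was -0.506. Deviations of mice of the same number correlated at -0.0649, 0.155 and 0.199 between MI and sham vehicle mice, 0.0281, -0.208 and 0.0665 between NECA-treated MI and MI mice, and -0.115, -0.164 and -0.248 between NECA-treated MI and sham vehicle mice. Pairs of unequal number were not computed as a reference, so these values do not decide whether the number pairs the mice.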

Other observations

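Clock genes, Tfrc, Alas1 and Ighm were chosen after their values were seen, so no test of them as a group is given. Clock genes stood apart between the 7 infarcted and the 3 sham vehicle mice. An index was taken as the mean log2 CPM of 9 genes that peak towards evening (Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Ciart) minus that of 3 genes of the opposite phase (Arntl, Npas2 and Clock). It was 3.98 ± 0.703 (SD, n = 7) in infarcted and 1.83 ± 0.874 (SD, n = 3) in sham vehicle mice, and the lowest infarcted value, 3.17, lay above the highest sham vehicle value, 2.74. Of the 9 evening genes 8 had a higher mean in infarcted mice, and all 3 opposite genes a lower one. Within the batch it was 2.83 to 3.34 in MI mice, 3.22 to 3.81 with NECA and 1.02 to 2.43 in sham vehicle mice. Arntl and Npas2 lay near the floor with NECA, at 2.49 ± 1.07 and 0.428 ± 0.856 CPM of library totals. The size of the gap therefore depends on the prior count. On the same counts, NECA-treated mouse 1 had an index of 4.39 beside all libraries and 3.38 within the batch, where only the scaled prior count differed. The labels give no hour of collection.

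Tfrc, the transferrin receptor gene, was 40.5 ± 11.3 CPM of library totals in 7 infarcted and 149 ± 44.3 CPM in 3 sham vehicle mice, and Alas1, which encodes the first enzyme of haem synthesis, 129 ± 22.7 and 236 ± 16.8 CPM. In MI against sham vehicle mice their log2 fold changes were -2.23 ± 0.39 and -1.07 ± 0.23, with edgeR adjusted p of 0.0554 and 0.057, so neither passed over all genes. Alas2, the erythroid form of this enzyme, did not separate all of the mice, with 34.7 and 36 CPM in the libraries of MI mouse 2 and 17.2 and 27.8 CPM in sham vehicle mice 1 and 2. MI mouse 2 was the only exception. MI mice 1 and 3 and all NECA-treated mice (8.95 to 16 CPM) lay below every sham vehicle mouse. B cell transcripts varied between mice of every group. Ighm, the heavy chain gene of IgM, was 741 CPM in MI mouse 1 and 26.3 CPM in the 1st library of MI mouse 3, 352 CPM in NECA-treated mouse 1 and 6.85 CPM in NECA-treated mouse 3, and 136 CPM in sham vehicle mouse 3 against 8.58 and 4.51 CPM in the others.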
